A study of Homo sapiens with 12 samples.

How the data were processed

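Gene expression was measured by RNA sequencing in 2 human multiple myeloma cell lines, U266 and MM.1S, each exposed for 6 h to the solvent DMSO or to 6 µM IT848, a compound the labels describe as an NF-kB inhibitor. The 4 groups held 3 libraries each, 12 in all. Cells grew in RPMI medium with fetal bovine serum, total RNA was taken with a column kit that also recovers DNA, and paired-end libraries were sequenced on an Illumina HiSeq, per the labels' protocols. One line of the series description names exome sequencing, whereas the series type and the library labels give expression profiling of RNA, which is what the tables hold. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values rest on the spread between these libraries, whether biological or technical.

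Per the submitters' processing notes, reads were handled with bcl2fastq, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 on the hg19 build. The strand setting, the treatment of reads with several alignments and the annotation release are not given in the sources used here. Each deposited table lists 51780 RefSeq transcripts of 25680 gene symbols with 3 values. The count is, per the file headers, the number of reads the authors assigned to the transcript. The deposited FPKM is that count scaled to transcript length and library total, and served here only to recover transcript length. The deposited TPM is scaled by the authors to 1e+06 per library and was used only as a check.

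In these tables a read was counted for every transcript it overlapped. Transcripts with more than 1000 counts over all libraries were compared, for the 6176 symbols with several of them. The least counted of these had a median of 0.982 of the counts of the most counted. Isoforms with fewer counts were left out, which can raise this ratio. Counts of all transcripts of a symbol were summed per gene, as fixed in the design, so a sum repeats reads in proportion to the number of isoforms. Levels of different genes are therefore not on a common scale. Genes that overlap, antisense partners and readthrough symbols such as PRR5-ARHGAP8 can share reads and are uncertain. So are families with near-identical copies, such as HSPA6, CCL3, CCL4, RASA4, FTL, HSP90AA1 and the ribosomal protein genes. Depending on how reads with several alignments were treated, these families can share or lose reads. Symbols were matched to the GRCh38.p14 annotation for current names and gene types alone: 25088 matched by transcript, 250 by symbol and 201 by an older symbol, and 141 stayed unmatched. No hg19 annotation was used here, so no coordinates are given.

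Total transcript counts were 50627690 to 72039748 per library. With 1 transcript per gene, the totals were 22887470 to 32913398, which is closer to the number of reads. Counting error is therefore small for most genes named, and the floor for a gene with no count in a group was set at 3 counts per library, 0.0478 to 0.0538 CPM by group. Reads were not marked with molecular identifiers, so such floors cover counting error only. As sums repeat reads, 3 counts can be fewer than 3 reads for a gene with several transcripts.

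The main test was edgeR's quasi-likelihood F test with robust estimation on all 12 libraries, a mean per group, TMM scaling and the default expression filter with a minimum count of 10, which left 16782 genes. Contrasts were IT848 against DMSO in each line, the difference of these responses (MM.1S minus U266), and MM.1S against U266 under DMSO. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a change was called at an adjusted p below 0.05. Levels are TMM-scaled CPM, given as mean ± SD of 3 libraries, and log2 fold changes are given ± SE. Overlap of the calls of both lines was set against the product of their numbers with a one-sided Fisher's exact test. The lines share no library.

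Gene lists were tested with camera at a correlation of 0.01, adjusted over the lists with at least 3 tested genes, with camera at an estimated correlation and fry beside it. Of 947 entries in 34 lists, 931 matched a symbol in the tables. The lists covered an 11-gene NF-kB index of myeloma cells, NF-kB targets and pathway components, stress programmes (NRF2, ATF4, heat shock, endoplasmic reticulum chaperones, metallothioneins, proteasome), growth and cell cycle (ribosome biogenesis, ribosomal proteins, G1/S, G2/M, histones), p53 targets and the BCL2 family, plasma cell identity, IL6-STAT3, interferon and immediate early genes, metabolism (cholesterol, fatty acids, hypoxia and glycolysis, respiratory chain, lysosome and autophagy, aryl hydrocarbon receptor), and markers of T and NK, myeloid, stromal, epithelial and erythroid cells and of the 2 lines. Some lists share genes: 8 of the 11 index genes and 15 of the 43 tested NF-kB targets are also in another list. The mitochondrially encoded genes, and IGHE, IGHA1 and TRAC of other lists, were not analysed here.

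The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, per line, the 10 highest and 10 lowest log2 fold changes among called protein-coding genes with a mean CPM of at least 5 and no overlap between treated and control libraries, the 11 index genes, and up to 4 members of each list by adjusted p. It also named the 8 highest and 8 lowest differences between the lines, the 8 largest shared changes per direction, and the genes characteristic of each line. All genes of the ranked parts and the index are named below, while the list members named are a part of those the rule gives, picked after their values were seen.

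Alternatives were other scalings (RLE, upper quartile, totals), other filters (none beyond 1 count, or a CPM of at least 1 in 3 libraries), DESeq2 and limma-voom, each line alone, the replicate number as a block, a 2-fold minimum, a test against a 1.2-fold change, each transcript as deposited, and leaving out each library. Added after seeing the data were the most counted transcript of each gene, a fit without 2 libraries that held reads of the other line, and a fit with each library's trend against transcript length taken out. Length was available for 46311 transcripts.

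The tests were tried on simulated data with 200 changed genes. That is fewer than the 1512 to 13868 called in the real data, where the adjusted threshold is therefore laxer. The shares below thus do not carry over to the real data. In the U266 contrast, over 16610 genes, 58.2% of 1.5-fold, 82.1% of 2-fold and 90.9% of 4-fold changes were recovered, with 11 false calls among 165. In the MM.1S contrast the shares were 60.3%, 71.2% and 93.9%, in the difference between lines 55.2%, 70.1% and 84.8%, and in the line comparison, over 16400 genes, 55.2%, 77.6% and 90.9%. These shares are edgeR's, with 8 false calls among 158 in MM.1S and 6 among 146 for the difference. DESeq2 made more false calls, 30 among 184 in U266, 23 among 174 in MM.1S and 25 among 169 for the difference. The simulated counts were drawn with edgeR's own dispersions, which can favour edgeR, and held no reads of another line. With a length trend of assumed size added to the simulated MM.1S DMSO libraries, over 16587 genes, the fit without a length term made 2065 false calls and the fit with the trend taken out 12. A list of 40 genes shifted by 1.2-fold was found by all 3 list tests with 0 other lists called. The simulated genes were drawn independently of each other, so this does not test false list calls where genes are correlated. Library pairs within a group had a chi-square per degree of freedom of 2.00 to 25.7 over 12 pairs, so none was a copy of another. Whether both mates of a read pair were counted is not known. Values near 2.00 therefore do not rule out repeat sequencing of the same library. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.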

Results

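RNA of the multiple myeloma lines U266 and MM.1S was profiled after 6 h with DMSO or 6 µM IT848, 3 libraries per group. U266 is an IgE-secreting line driven in part by cyclin D1 and autocrine IL6, and MM.1S is an IgA myeloma line that overexpresses the transcription factor MAF. The series asked how an NF-kB inhibitor alters the transcriptome of these cells. The libraries held 50627690 to 72039748 transcript counts and detected 18259 to 20966 genes each. A pair of libraries stood apart. In IT848 replicate 1 of U266, 11 genes that are high in MM.1S and near 0 in U266 DMSO were all detected. Their sum was 0.883% of the MM.1S level, against 0.0979% and 0.0957% in IT848 replicates 2 and 3. In DMSO replicate 2 of MM.1S, 36 genes that are high in U266 and near 0 in MM.1S DMSO replicates 1 and 3 were all detected. Their sum was 0.458% of the U266 level, against 0.0628 to 0.104% in the IT848 libraries of MM.1S, which took no part in choosing these genes. Counts without these 2 libraries are given beside the main counts.

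Before treatment the lines differed widely and carried their known marks. CCND1, which encodes cyclin D1, stood at 506 ± 2.79 CPM in U266 and 4.85 ± 1.23 in MM.1S (SD, n = 3), and IL6, a growth factor of plasma cells, at 4.32 ± 0.0641 and 0.106 ± 0.00689. MAF was at 36.6 ± 0.960 CPM in U266 and 885 ± 53.6 in MM.1S, the MAF-controlled integrin gene ITGB7 at 276 ± 12.5 and 9247 ± 59.6, and CCND2, encoding cyclin D2, at 130 ± 3.62 and 405 ± 19.0. All 5 were called by edgeR's quasi-likelihood test. Of the 11 NF-kB index genes, 6 were higher in MM.1S and 3 lower (6 and 3 adjusted over the list alone). PLEK, encoding the hematopoietic signalling protein pleckstrin, was 4.02 ± 0.10 higher on the log2 scale, while BIRC3, an inhibitor of apoptosis, and NFKBIA, which encodes the NF-kB inhibitor IkBa, were at −1.19 ± 0.04 and −1.10 ± 0.05.

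Several groups were set differently in the untreated lines. Of 39 interferon-stimulated genes, 26 were lower and 10 higher in MM.1S (26 and 10 adjusted over the list alone, median −1.79). ATF4 and integrated stress response genes were lower in MM.1S for 36 of 43 and higher for 6 (36 and 6 adjusted over the list alone), and lysosome and autophagy genes for 30 of 39 and 5 (30 and 5 adjusted over the list alone). Plasma cell identity genes were higher in MM.1S for 21 of 30 and lower for 8 (21 and 8 adjusted over the list alone). These lists were called by camera (adjusted p of 1.1e-05, 1.7e-09, 1.7e-04 and 0.0044), and none of the 4 with an estimated correlation (adjusted p of 0.185, 0.0648, 0.0648 and 0.128). In all, 13868 of 16782 genes differed between the lines (6806 higher in MM.1S, 7062 lower), and 13520 without the 2 libraries.

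In U266, IT848 raised stress response genes most. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 26.6-fold, from 29.3 ± 0.461 to 781 ± 70.3 CPM (SD, n = 3; log2 fold change 4.74 ± 0.09). HSPA6, a heat-inducible HSP70 gene with a near-identical copy, rose from 0.188 ± 0.0569 to 106 ± 20.7 CPM (9.11 ± 0.21). Genes of early transcription factors rose with them: EGR1 by 2.10 ± 0.14, FOS by 1.69 ± 0.15 and JUN by 1.60 ± 0.05. Among the falls were those of APOL3, an apolipoprotein L gene (−0.94 ± 0.06), and POU2F2, which encodes the B cell factor OCT2 (−0.88 ± 0.07). In total 1512 genes changed by edgeR's quasi-likelihood test, 676 up and 836 down, with a median size of 0.32 on the log2 scale, and 96 by at least 2-fold (90 up, 6 down). The 90 rises can include MM.1S genes near 0 in U266, such as EYA1, since IT848 replicate 1 held reads of MM.1S. The 2-fold count was not repeated without that library.

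**Figure D1:**
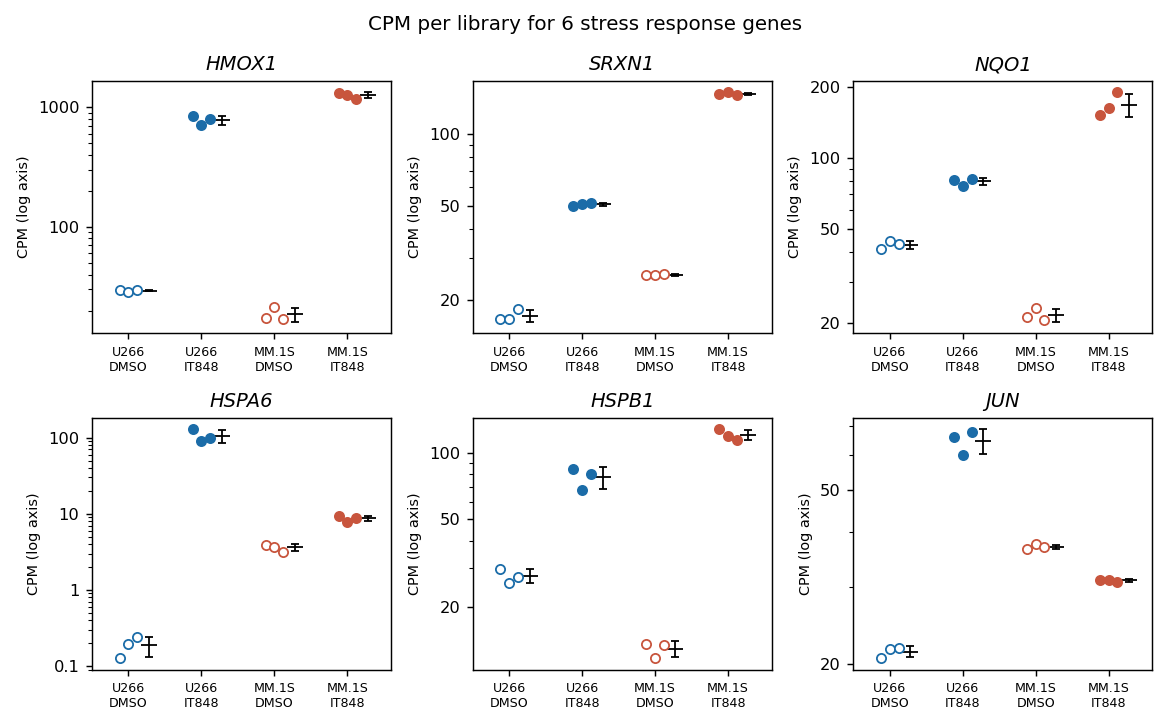
CPM of 6 stress response genes per library (points; log axis) in U266 (blue) and MM.1S (orange), with DMSO as open and IT848 as filled points, and mean ± SD of 3 libraries as black bars beside them. HMOX1 rose in both lines, to 781 CPM in U266 and 1253 CPM in MM.1S, whereas JUN rose in U266 from 21.4 to 64.6 CPM and fell in MM.1S from 37.1 to 31.1 CPM.

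Heat shock genes rose in U266 for 20 of 26 and fell for 0 (22 and 0 adjusted over the list alone; camera adjusted p 2.4e-110). Besides HSPA6 they included HSP90AA1, the inducible HSP90 (1.38 ± 0.09), HSPH1, a nucleotide exchange factor (1.04 ± 0.04), and HSPD1, the mitochondrial chaperonin (0.82 ± 0.04). The co-chaperone gene BAG3 (1.58 ± 0.08), HSPB1, a small heat shock protein (1.49 ± 0.08), and SERPINH1, a collagen chaperone (from 16.1 ± 0.742 to 45.4 ± 5.54 CPM), also rose. Of 38 oxidative stress genes controlled by NRF2, 21 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p 7.2e-69), among them SRXN1, which encodes sulfiredoxin (1.55 ± 0.05), TXNRD1, thioredoxin reductase (0.85 ± 0.04), and SQSTM1, the autophagy receptor p62 (0.84 ± 0.04). ATF4 and integrated stress response genes rose for 37 of 43 and fell for 0 (40 and 0 adjusted over the list alone; camera adjusted p 2.8e-57), with CTH, an enzyme of cysteine synthesis, at 1.01 ± 0.07, PPP1R15A, a phosphatase subunit for eIF2a, at 0.91 ± 0.07, ATF3 at 0.87 ± 0.06 and the pseudokinase gene TRIB3 at 0.77 ± 0.06.

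Of 36 immediate early genes in U266, 13 rose and 4 fell (15 and 5 adjusted over the list alone; camera adjusted p 2.3e-15). Beside EGR1, FOS and JUN, the rises included the MAPK phosphatase gene DUSP1 (1.58 ± 0.14). Among 34 p53 targets, 10 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p 7.5e-05). The rises included GADD45A, a growth arrest gene (0.90 ± 0.05), and the stress cytokine gene GDF15 (1.52 ± 0.17), both also known to respond to ATF4. Proteasome subunit genes rose for 10 of 33 and fell for 0 (12 and 0 adjusted over the list alone), with PSMD11 at 0.36 ± 0.04 and a list median of 0.12. The adjusted p was 2.4e-07 by camera and 0.410 with an estimated correlation. Lysosome and autophagy genes rose for 9 of 39 and fell for 7 (13 and 7 adjusted over the list alone), with GABARAPL1, an autophagosome protein gene, at 0.60 ± 0.06. The adjusted p was 0.0027 by camera and 0.0760 with an estimated correlation.

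The plasma cell programme fell in U266. Of 30 plasma cell identity genes, 18 fell and 2 rose (18 and 2 adjusted over the list alone; camera adjusted p 1.0e-13). IRF4, the factor on which myeloma cells depend, fell by 0.58 ± 0.05, SDC1, which encodes the surface proteoglycan CD138, by 0.54 ± 0.04, and IKZF1, the lymphoid factor Ikaros, by 0.32 ± 0.04. SLAMF7, a surface receptor used as an antibody target in myeloma, rose by 0.47 ± 0.03. TNFRSF17, which encodes the receptor BCMA, fell by 0.53 ± 0.07. Other large falls were of WISP1, a secreted matrix protein gene (−0.92 ± 0.10), SMPD3, a neutral sphingomyelinase (−0.85 ± 0.11), CD180, a toll-like receptor homologue of B cells (−0.84 ± 0.10), the readthrough symbol PRR5-ARHGAP8 (−0.80 ± 0.12), MPP2, a membrane scaffold gene (−0.80 ± 0.15), and MYADM (−0.78 ± 0.10).

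Growth and cell cycle genes showed few calls in U266. Of 42 G1/S genes 2 rose and 2 fell, and of 42 ribosome biogenesis genes 2 rose and 2 fell (2 and 2 adjusted over the list alone in each). The medians of 40 G2/M genes and 53 ribosomal protein genes were −0.02 and 0.06, and neither list was called (camera adjusted p 0.553 and 0.110), although the ribosomal protein list was without IT848 replicate 2 (0.0300). Interferon-stimulated genes rose for 2 of 39 and fell for 6 (4 and 8 adjusted over the list alone), and cholesterol synthesis genes for 1 and 4 of 24 (1 and 5 adjusted over the list alone). Respiratory chain genes rose for 0 of 48 and fell for 1 (0 and 1 adjusted over the list alone), and IL6-STAT3 targets for 5 and 6 of 22 (6 and 7 adjusted over the list alone).

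The U266 count was 924 genes without the 2 libraries that held reads of the other line and 986 without DMSO replicate 3. At an unadjusted p below 0.05, 3485 genes passed, and treated and control libraries did not overlap for 28.9% of genes, where chance gives 10%. A pair of the ranked falls lost their calls in other settings, at fold changes of the same direction. The call of LGALS12, a galectin gene (−0.95 ± 0.25), ended with all libraries by DESeq2 (adjusted p 0.712; −0.96) and without the low-count filter (0.0609), and it ended without DMSO replicate 1 or 2 or any IT848 replicate (adjusted p of 0.164, 0.129, 0.0725, 0.107 and 0.118 by edgeR's quasi-likelihood test), with log2 fold changes of −0.83 to −0.98. That of CD300LF, an inhibitory receptor gene (−0.81 ± 0.19), ended without DMSO replicate 2 or 3 or IT848 replicate 1 or 2 (0.115, 0.122, 0.0863 and 0.0931), at −0.66 to −0.80, and without the 2 libraries (0.0784).

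In MM.1S many oxidative stress genes rose. HMOX1 rose 67.5-fold, from 18.6 ± 2.44 to 1253 ± 71.4 CPM (SD, n = 3; log2 fold change 6.08 ± 0.10). SLCO2B1, an organic anion transporter gene, rose from 0.306 ± 0.441 to 10.2 ± 2.35 CPM (5.26 ± 0.46), HSPB1 by 3.22 ± 0.09, P4HA2, a collagen prolyl hydroxylase gene, by 3.11 ± 0.11, and NQO1, which encodes a quinone reductase, by 2.95 ± 0.08. ABCG1, a cholesterol exporter gene, fell by 1.56 ± 0.10, and CXCR4, the chemokine receptor gene for marrow homing, from 68.9 ± 3.54 to 29.4 ± 1.45 CPM (−1.23 ± 0.05). By edgeR's quasi-likelihood test 6430 genes changed, 3141 up and 3289 down, with a median size of 0.36, and 486 by at least 2-fold (279 up, 207 down).

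Of the 38 NRF2 genes, 31 rose and 1 fell in MM.1S (32 and 2 adjusted over the list alone; camera adjusted p 1.2e-120), with a median of 1.09. They included FTL, ferritin light chain (2.35 ± 0.04), SRXN1 (2.52 ± 0.05), SQSTM1 (1.89 ± 0.04) and TXNRD1 (1.86 ± 0.04). SLC7A11, the cystine importer gene, rose by 2.12 ± 0.07, and ABCB6, a porphyrin transporter gene, by 2.37 ± 0.05. Heat shock genes rose for 20 of 26 and fell for 0 (22 and 0 adjusted over the list alone; camera adjusted p 8.5e-33), with HSP90AA1 at 2.46 ± 0.09, HSPH1 at 1.08 ± 0.04, HSPD1 at 0.87 ± 0.04, and DNAJA4, an HSP40 gene, at 2.37 ± 0.14. Of 43 ATF4 genes 24 rose and 3 fell (25 and 3 adjusted over the list alone; camera adjusted p 6.9e-09), CTH by 1.23 ± 0.09 among them.

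All 33 proteasome genes rose in MM.1S (33 adjusted over the list alone; camera adjusted p 1.2e-27), with a median of 0.55, PSMC4 at 0.64 ± 0.04 and PSMD11 at 0.58 ± 0.04. Interferon-stimulated genes rose for 22 of 39 and fell for 3 (23 and 3 adjusted over the list alone; camera adjusted p 3.0e-08). MX1, an antiviral GTPase gene, rose by 1.49 ± 0.06, IRF9, a subunit of the interferon-activated factor, by 0.98 ± 0.08, and BST2, which encodes tetherin, by 0.83 ± 0.04. Lysosome and autophagy genes rose for 22 of 39 and fell for 2 (22 and 3 adjusted over the list alone; camera adjusted p 4.6e-11), with GABARAPL1 at 1.81 ± 0.06 and the lysosomal glycoprotein gene GPNMB at 1.30 ± 0.06. Of 24 cholesterol synthesis genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p 2.9e-05), with INSIG1, a sterol sensor partner, at 0.54 ± 0.04 and HMGCS1, a synthase of the mevalonate pathway, at 0.46 ± 0.04.

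DNA replication genes fell in MM.1S. Of 42 G1/S genes, 39 fell and 0 rose (41 and 0 adjusted over the list alone; camera adjusted p 1.1e-32). DTL, a ubiquitin ligase subunit of S phase, fell by 0.75 ± 0.04, the uracil glycosylase gene UNG by 0.75 ± 0.04, CLSPN, the checkpoint adaptor claspin, by 0.73 ± 0.04, and MCM3, of the replicative helicase, by 0.66 ± 0.03. Of 42 ribosome biogenesis genes bound by MYC, 31 fell and 1 rose (34 and 1 adjusted over the list alone; camera adjusted p 8.1e-13), including the nucleolar gene NOLC1 (−0.63 ± 0.04). G2/M genes rose for 18 of 40 and fell for 3 (19 and 3 adjusted over the list alone), including CCNB1, cyclin B1, by 0.54 ± 0.07. The adjusted p was 0.0113 by camera and 0.629 with an estimated correlation.

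Plasma cell genes fell for 16 of 30 and rose for 4 in MM.1S (17 and 6 adjusted over the list alone; camera adjusted p 4.8e-08), with SDC1 at −1.04 ± 0.04, IKZF1 at −0.61 ± 0.04, IRF4 at −0.57 ± 0.05 and SLAMF7 at 0.43 ± 0.03. Of 22 IL6-STAT3 targets, 7 fell and 4 rose (7 and 4 adjusted over the list alone), with the kinase gene PIM1 at −1.01 ± 0.04. The adjusted p was 0.0145 by camera and 0.197 with an estimated correlation. Immediate early genes fell for 14 of 36 and rose for 5 (14 and 5 adjusted over the list alone), and the list was not called (camera adjusted p 0.480). Of 34 p53 targets 8 rose and 9 fell (9 and 9 adjusted over the list alone; camera adjusted p 0.943), among them the death receptor gene FAS (0.63 ± 0.07) and TP53INP1, an autophagy and stress gene (−0.79 ± 0.05). Further large falls were of RASA4, a Ras GTPase activator (−1.49 ± 0.10), HSPG2, perlecan (−1.44 ± 0.12), NAV1, a neuron navigator (−1.41 ± 0.09), and BZRAP1, a binding protein of the mitochondrial benzodiazepine receptor (−1.40 ± 0.19). They also included the amine oxidase gene AOC3 (−1.30 ± 0.17), the chemokine receptor gene CX3CR1 (−1.28 ± 0.11), CIITA, the master regulator of MHC class II genes (−1.24 ± 0.08), and HIVEP3, a zinc finger gene (−1.18 ± 0.09).

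**Figure D2:**
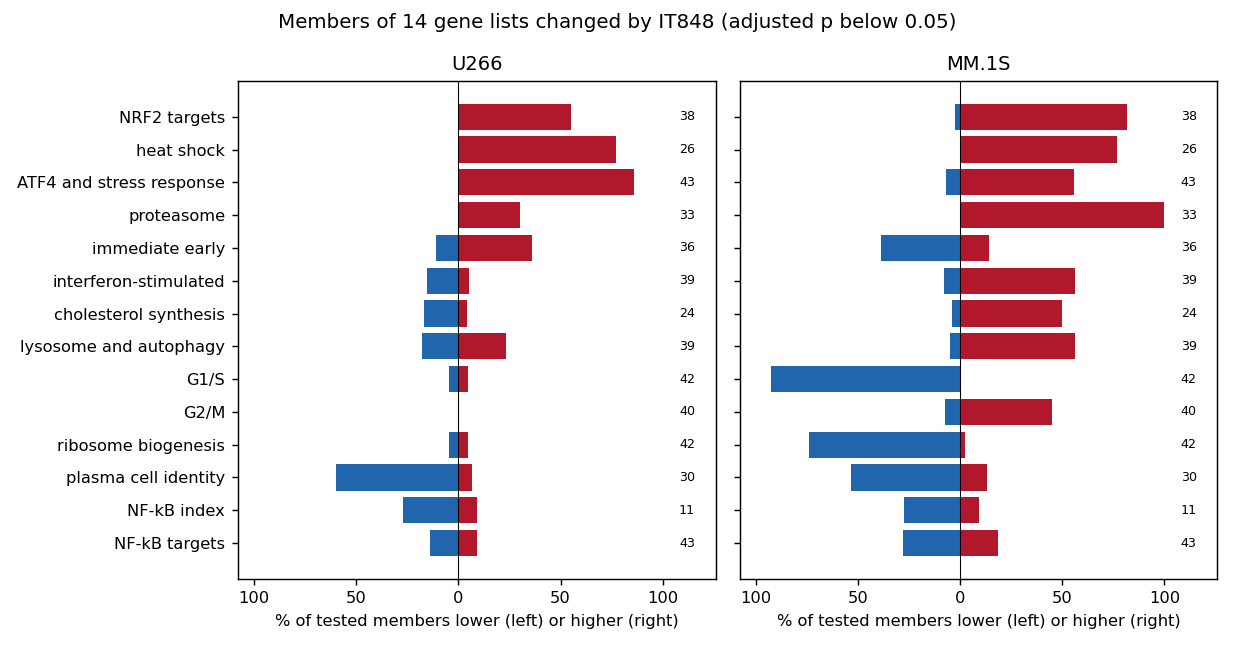
Share of tested members of 14 gene lists called higher (red, right) or lower (blue, left) with IT848 in each line, in percent, with the number of tested members at the right edge of each panel. All 33 proteasome genes were higher and 39 of 42 G1/S genes lower in MM.1S, against 10 higher and 2 lower in U266.

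Ribosomal protein genes rose for 48 of 53 in MM.1S (49 adjusted over the list alone; median 0.40), with an adjusted p of 5.0e-08 by camera and 0.629 with an estimated correlation. Respiratory chain genes rose for 25 of 48 and fell for 2 (26 and 2 adjusted over the list alone), with an adjusted p of 0.0066 by camera, 0.845 with an estimated correlation and 0.0894 without IT848 replicate 3. Both groups have short transcripts (median 786 and 955 bases, against 2834 for all genes). Across 9380 genes, Spearman's correlation of transcript length with a library's deviation from the MM.1S mean was 0.168 to 0.451 in the DMSO libraries and −0.484 to 0.0285 in the IT848 libraries, and ribosomal protein genes held 3.01 to 3.46% and 3.56 to 4.62% of counts. In U266, across 9260 genes, the correlations were 0.0054 to 0.216 in the DMSO libraries and −0.277 to 0.123 in the IT848 libraries, so the shift went the same way with overlap. With that trend taken out, a fit chosen after seeing the data, the medians were 0.10 for ribosomal protein, 0.04 for respiratory chain, 0.41 for proteasome and −0.47 for G1/S genes.

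The MM.1S count was 5387 without the 2 libraries that held reads of the other line. With the length trend taken out 6367 genes were called, 5213 of them among the 6430. At an unadjusted p below 0.05, 7840 genes passed, and treated and control libraries did not overlap for 47.2% of genes, where chance gives 10%. With an estimated correlation, 7 of the 10 lists called in U266 stayed called (NRF2, ATF4, heat shock, p53, plasma cell, immediate early and aryl hydrocarbon receptor genes), and 11 of the 16 in MM.1S (NRF2, ATF4, heat shock, proteasome, ribosome biogenesis, G1/S, plasma cell, interferon, cholesterol, lysosome and aryl hydrocarbon receptor genes). Their adjusted p by camera was then much larger, at 3.1e-05 to 0.0324 in U266 and 4.4e-06 to 0.0454 in MM.1S. In MM.1S the proteasome (0.0424), interferon (0.0454) and aryl hydrocarbon receptor lists (0.0454) passed narrowly.

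The labels describe IT848 as an NF-kB inhibitor, so genes that NF-kB controls were taken here as a readout. Neither NF-kB list moved as a set in a common direction. Over all genes tested, 9.01% were called in U266 and 38.3% in MM.1S. In U266, 1 of the 11 index genes rose and 3 fell (1 and 4 adjusted over the list alone), with a median of −0.03. NFKBIA rose by 0.60 ± 0.05, while WNT10A fell by 0.33 ± 0.06, BIRC3 by 0.16 ± 0.04 and MALT1, a paracaspase gene of the pathway, by 0.16 ± 0.04. In MM.1S, 1 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of −0.04: PLEK rose by 0.44 ± 0.07, and TNFAIP3, encoding the NF-kB feedback inhibitor A20, fell by 0.25 ± 0.04, CD74, the invariant chain, by 0.19 ± 0.06 and WNT10A by 0.18 ± 0.06. NFKB2, IL2RG, NFKBIE and RELB were called in neither line, with log2 fold changes of −0.03, 0.00, −0.06 and 0.01 in U266 and 0.08, −0.04, −0.15 and 0.15 in MM.1S. RELB in MM.1S lay near the threshold. By edgeR's quasi-likelihood test it was called higher with upper quartile scaling (adjusted p 0.0379), in a fit of MM.1S alone (0.0357), per transcript (0.0362), with 1 transcript per gene (0.0398) and without IT848 replicate 1 (0.0424), and by DESeq2 (0.0434). NFKBIE in MM.1S was called lower with the length trend taken out (0.0466), and NFKB2 higher without IT848 replicate 3 (0.0364). BIRC3 in MM.1S was called lower with total scaling (−0.11, adjusted p 0.0450) and without DMSO replicate 3 (0.0449), MALT1 in MM.1S higher with the length trend taken out (0.0057), and TNFAIP3 in U266 lower by DESeq2 (−0.12, 0.0447).

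**Figure D3:**
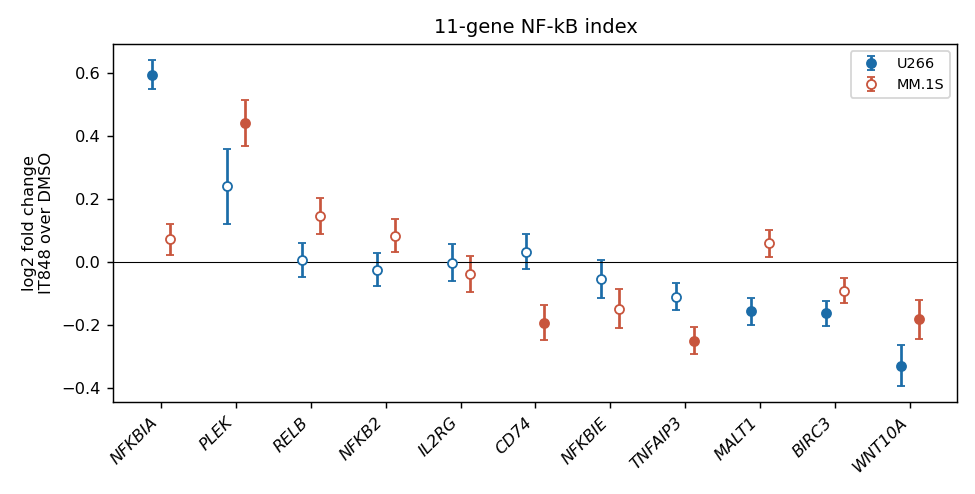
Log2 fold change ± SE (IT848 over DMSO, n = 3 libraries per group) of the 11 NF-kB index genes in U266 (blue) and MM.1S (orange). Filled points are genes with an adjusted p below 0.05 by edgeR's quasi-likelihood test; values ran from −0.33 to 0.60 in U266 and from −0.25 to 0.44 in MM.1S.

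Of 43 NF-kB targets, 4 rose and 6 fell in U266 (5 and 8 adjusted over the list alone), and 8 rose and 12 fell in MM.1S (9 and 12 adjusted over the list alone). BCL3, an atypical IkB gene, fell in both lines (−0.43 ± 0.08 and −0.46 ± 0.08) and TNIP2, an A20 partner, rose in both (0.29 ± 0.06 and 0.19 ± 0.05, the latter with an adjusted p of 0.0692 by edgeR's quasi-likelihood test without DMSO replicate 1 of MM.1S, and 0.0035 at the lowest over the settings). In MM.1S the chemokine genes CCL3 (1.70 ± 0.06, from 183 ± 16.8 to 594 ± 33.4 CPM) and CCL4 (1.27 ± 0.10) rose. CCL3 in U266 was near the threshold (−0.20; adjusted p 0.0530 by edgeR's quasi-likelihood test), and was called lower by DESeq2 (0.0194) and limma-voom (0.0435), with U266 fitted alone (0.0028), with total scaling (0.0368), a minimum of 1 CPM (0.0446), per transcript (0.0358), with 1 transcript per gene (0.0281) and with the length trend taken out (0.0041). In MM.1S NFKBIZ, encoding another nuclear IkB, fell by 0.67 ± 0.08 and the survival gene BCL2L1 by 0.37 ± 0.04. GADD45B, a stress gene, rose in U266 (0.38 ± 0.06) and fell in MM.1S (−0.42 ± 0.06). Of 32 pathway components, 1 rose and 2 fell in U266 (1 and 3 adjusted over the list alone), and 3 rose and 8 fell in MM.1S (3 and 8 adjusted over the list alone), including the TNF receptor gene TNFRSF1B (−0.94 ± 0.08). For the components camera gave an adjusted p of 0.902 in U266 and 0.480 in MM.1S, while fry, which does not compare a list with other genes, called them lower in MM.1S (adjusted p 0.0239, within 0.0239 to 0.939 over the settings).

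Camera gave adjusted p-values of 0.937 for the index and 0.937 for the targets in U266, and 0.921 and 0.921 in MM.1S, and none of the 13 other settings in which each list was tested called it (adjusted p of 0.451 to 0.997). The lists were not tested with upper quartile or total scaling, other filters, DESeq2 or limma-voom. All of these tests ask for a common direction. Without regard to direction, fry gave the index and the targets an unadjusted p of 3.6e-10 and 6.7e-10 in U266. In MM.1S it gave 1.5e-06 and 1.7e-10. Fry does not compare a list with other genes, so members changed, but not shown to do so more than other genes. The 95% interval of the log2 fold change lay above −1, which excludes a 2-fold fall, for all 11 index genes in both lines, and for 40 of the 43 targets in U266 and 41 in MM.1S. Several small index changes lost their calls in other settings by edgeR's quasi-likelihood test, at fold changes of the same direction. The call of BIRC3 in U266 ended without DMSO replicate 2 or IT848 replicate 1 or 3 (adjusted p of 0.05004, 0.0748 and 0.0589; log2 fold change −0.15 to −0.16), without the 2 libraries (0.0942) and with the length trend taken out (0.0539). That of MALT1 ended without DMSO replicate 1, 2 or 3 or IT848 replicate 1 or 3 (0.0583, 0.131, 0.0626, 0.161 and 0.118; −0.12 to −0.17), without the 2 libraries (0.214) and without the low-count filter (0.0557). That of WNT10A in MM.1S ended without DMSO replicate 1 or 2 or IT848 replicate 2 or 3 (0.0800, 0.0758, 0.0811 and 0.112; −0.14 to −0.18) and without the 2 libraries (0.0863), and the call of CD74 in MM.1S without IT848 replicate 2 or 3 (0.0535 and 0.0646; −0.18 and −0.15).

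Both lines changed 887 genes in the same direction. Among genes with a mean CPM of at least 5 in each line, the 8 largest shared rises, by the smaller of the 2 changes, were of HMOX1, SRXN1, DGKG, a diacylglycerol kinase gene (1.57 ± 0.10 in U266 and 1.53 ± 0.07 in MM.1S), HSPB1, HSP90AA1, HSPA6 (1.26 ± 0.15 in MM.1S), AGPAT9, a glycerolipid synthesis gene (1.36 ± 0.13 and 1.24 ± 0.12), and P4HA2 (1.05 ± 0.11 in U266). The 8 largest shared falls were of APOL3 (−0.98 ± 0.06 in MM.1S), POU2F2 (−0.79 ± 0.08 in MM.1S), MPP2 (−0.77 ± 0.13 in MM.1S), and CPNE5, a copine gene (−0.77 ± 0.06 and −0.90 ± 0.07). With them fell the chemokine receptor gene CCR2 (−0.63 ± 0.07 and −0.86 ± 0.08), INPP4A, a phosphoinositide phosphatase gene (−0.62 ± 0.05 and −0.61 ± 0.05), SH2B2, an adaptor gene (−0.71 ± 0.06 and −0.61 ± 0.06), and GLDC, a glycine-degrading enzyme (−0.59 ± 0.06 and −0.66 ± 0.06). XBP1, a plasma cell and secretory pathway factor, also fell in both (−0.39 ± 0.04 and −0.56 ± 0.04).

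The shared rises numbered 388, against 127 expected from independent lists (odds ratio 6.53, one-sided Fisher's exact test across genes, p = 2.3e-116), and the shared falls 499 against 164 (odds ratio 6.98, p = 1.8e-152). Another 143 genes were called in opposite directions. Of the 887, 596 had the larger change in MM.1S, and the difference between lines was called for 258. Over all 16782 genes the log2 fold changes correlated with Pearson's r of 0.12 and Spearman's rho of 0.25, across genes, which are not independent replicates. Without the 2 libraries that held reads of the other line the shared count was 550.

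**Figure D4:**
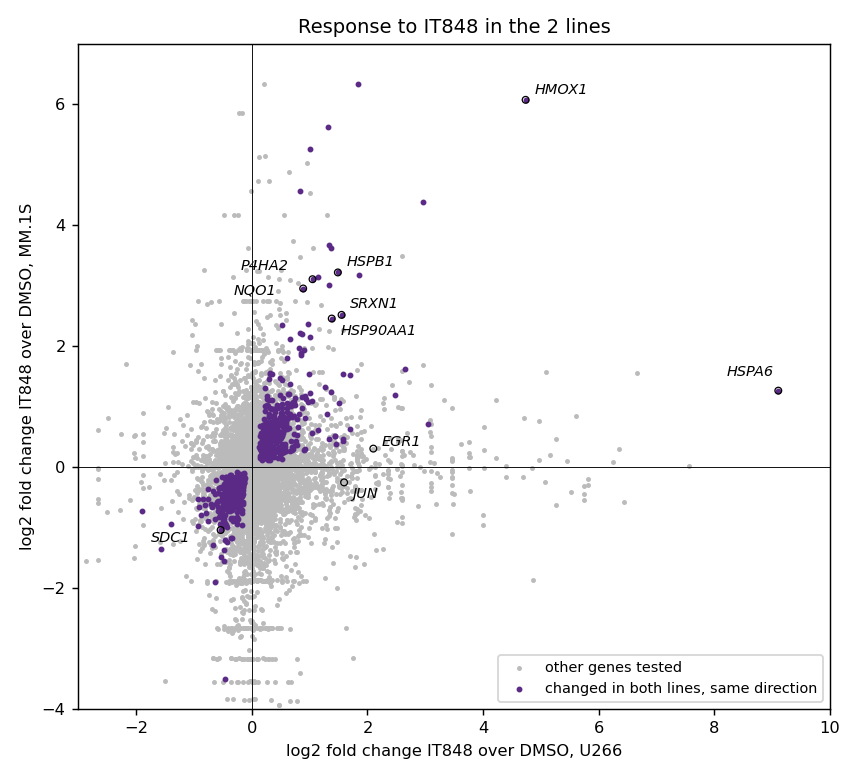
Log2 fold change with IT848 in MM.1S against that in U266 for 16728 of the 16782 genes tested (54 lie outside the axes), with the 887 genes changed in both lines in the same direction in purple. HMOX1 (4.74 and 6.08) lies far from 0 in both lines, while JUN (1.60 and −0.25) lies far from 0 in U266 alone; bands of grey points are genes with few counts.

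The responses themselves differed between the lines for 2924 genes, by the interaction contrast of edgeR's quasi-likelihood test. The MM.1S response was higher for SLCO2B1 (difference 4.25 ± 0.55), DNAJA4 (2.28 ± 0.20), the lncRNA HAGLR (2.19 ± 0.41), NCAM1, the adhesion molecule CD56 (2.15 ± 0.13), NQO1 (2.07 ± 0.10), P4HA2 (2.06 ± 0.16), TTC39A (1.95 ± 0.11) and LOC100132891 (1.94 ± 0.26). It was lower for HSPA6 (−7.84 ± 0.30), JUN (−1.85 ± 0.07) and EGR1 (−1.80 ± 0.30). By list, 29 of 38 NRF2 genes rose more in MM.1S and 2 less (29 and 2 adjusted over the list alone), 36 of 42 G1/S genes had a lower response in MM.1S and 0 a higher one (36 and 0 adjusted over the list alone), and 20 of 39 interferon-stimulated genes a higher and 1 a lower one (22 and 2 adjusted over the list alone). Heat shock genes split, with 6 of 26 higher and 8 lower (6 and 8 adjusted over the list alone).

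The remaining low differences of the ranked part were of genes near 0 in 1 line. EYA1, HRH2, FGFR2, LAMP5-AS1 and ARHGAP6 are MM.1S genes (119, 41.2, 13.5, 27.4 and 183 CPM under DMSO) with 0.402, 0.116, 0.119, 0.0608 and 0.877 CPM in U266 with IT848. ST6GAL2 and TP63 are U266 genes (39.0 and 40.7 CPM) with 0.234 and 0.0414 CPM in MM.1S DMSO and no count with IT848. The IT848 replicate 1 library of U266, which held reads of MM.1S genes, had 0.855 CPM of EYA1, 0.285 of HRH2, 0.134 of LAMP5-AS1 and 2.06 of ARHGAP6. FGFR2 was not highest there, with 0.168 CPM, against 0.189 in IT848 replicate 2 and 0 in IT848 replicate 3. With 3 summed counts per library as the floor of a group at 0, EYA1 was 7.97-fold over the floor with IT848 in U266. HRH2 was 2.29-fold, FGFR2 2.36-fold and LAMP5-AS1 1.204-fold over it there, and ST6GAL2 was 4.35-fold over it in MM.1S DMSO. A sum repeats a read for each isoform, so 3 counts can be fewer than 3 reads. These ratios are therefore not bounds for genes with several transcripts. They include the 2 libraries with reads of the other line. Without those libraries the ratio was 3.49-fold for EYA1, 1.87-fold for FGFR2 and 4.31-fold for ST6GAL2, and HRH2 and LAMP5-AS1 lay under the floor. IT848 replicates 2 and 3 of U266 also held reads of the 11 MM.1S marker genes, at 0.0979 and 0.0957% of their summed MM.1S level. For the MM.1S genes the ratios therefore describe what the libraries held and not U266 expression. Of the 5 MM.1S genes, the change in U266 passed edgeR's quasi-likelihood test for EYA1, and not without DMSO replicate 3 (adjusted p 0.0572) or the low-count filter (0.0785). The other 4 missed it (0.0524 to 0.102). Without IT848 replicate 3 all 4 passed (HRH2 0.0220, FGFR2 7.4e-04, ARHGAP6 0.0133, LAMP5-AS1 0.0218), and HRH2 also passed without IT848 replicate 2 (0.0428). By DESeq2, which made more false calls in data simulated with edgeR's dispersions, all 4 passed as well (0.0019, 4.5e-04, 0.0031 and 0.0088). HRH2, FGFR2 and LAMP5-AS1 each passed in further settings, among them limma-voom for HRH2 (0.0218), a minimum of 1 CPM for FGFR2 (0.0465) and counts per transcript for LAMP5-AS1 (0.0261). TP63 lay under the floor in both MM.1S groups.

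Of the 2924 differing responses, 1424 were higher in MM.1S and 1500 lower, and 323 differed by at least 2-fold. With all 12 libraries 5342 genes passed an unadjusted p below 0.05. Without the 2 libraries that held reads of the other line 1712 were called.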

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

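The tests of the transcript length trend, and the test of a U266 response as the source of MM.1S reads, were chosen only after the results were seen, as were the fits without 2 libraries and with the length trend taken out. The results below are differences between the responses of the lines, as MM.1S minus U266 on the log2 scale, called by the interaction contrast or, for lists, by camera.

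Among stress genes the difference was 1.34 for HMOX1, 0.97 for SRXN1, 2.07 for NQO1, 1.01 for TXNRD1, 1.05 for SQSTM1, 1.83 for FTL, 1.46 for SLC7A11, 1.39 for ABCB6, 0.71 for the NADPH-producing malic enzyme gene ME1, 1.73 for HSPB1, 1.08 for HSP90AA1 and 2.28 for DNAJA4. It was −7.84 for HSPA6, −1.16 for BAG3, −1.85 for JUN, −1.80 for EGR1, −1.06 for FOS, −1.11 for DUSP1, −0.98 for ATF3, −0.61 for PPP1R15A, −0.34 for TRIB3 and −0.63 for GADD45A. The TRIB3 difference had an adjusted p of 0.0813 by edgeR's quasi-likelihood test without the 2 libraries, within a range of 0.0014 to 0.0813 over the settings.

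For NF-kB genes and receptors the difference was −0.52 for NFKBIA, 0.22 for MALT1, 1.90 for CCL3, 1.17 for CCL4, −0.69 for NFKBIZ, −0.80 for GADD45B, −0.76 for TNFRSF1B and 0.80 for TNFRSF17. The MALT1 difference was lost without IT848 replicate 1 of U266, DMSO replicate 1 or 2 of MM.1S or IT848 replicate 2 of MM.1S (adjusted p of 0.0525, 0.0586, 0.0580 and 0.0527 by edgeR's quasi-likelihood test), and without the 2 libraries (0.108). For plasma cell, cytokine response and survival genes it was −0.55 for MAF, −0.79 for CCND2, −0.50 for SDC1, −0.29 for IKZF1, −0.93 for PIM1, −0.39 for BCL2L11, 0.58 for FAS and −0.72 for TP53INP1, and for interferon genes 1.48 for MX1, 0.71 for BST2 and 0.90 for IRF9.

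For growth genes the difference was −0.61 for MCM3, −0.69 for CLSPN, −0.66 for DTL, −0.58 for UNG, 0.51 for CCNB1, 0.22 for PSMD11, 0.52 for PSMC4 and −0.54 for NOLC1. For metabolism and lysosome genes it was 0.26 for INSIG1, 0.48 for HMGCS1, 1.204 for GABARAPL1 and 1.08 for GPNMB. Among the ranked genes it was 4.25 for SLCO2B1, 2.06 for P4HA2, 2.19 for HAGLR, 2.15 for NCAM1, 1.95 for TTC39A and 1.94 for LOC100132891, and −1.245 for ABCG1, −0.97 for RASA4, −1.07 for HSPG2, −1.60 for NAV1, −1.10 for BZRAP1, −1.248 for AOC3, −0.82 for CIITA, −1.19 for CXCR4 and −0.81 for HIVEP3. The BZRAP1 difference had an adjusted p of 0.0549 by edgeR's quasi-likelihood test without IT848 replicate 3 of MM.1S, within a range of 0.0028 to 0.0549 over the settings.

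Fitted differences of genes near 0 in a line were −7.55 for EYA1, −6.30 for HRH2, −6.21 for ST6GAL2, −6.19 for FGFR2, −4.85 for LAMP5-AS1, −4.50 for TP63 and −3.94 for ARHGAP6, which depend on the prior count and are no bounds. By edgeR's quasi-likelihood test the ST6GAL2 difference stayed called under the settings tried. The EYA1 difference had an adjusted p of 0.0534 without the low-count filter and was called under the other settings (2.0e-05 at the lowest). That of HRH2 was lost without DMSO replicate 2 or 3 of U266 (adjusted p of 0.05004 and 0.0521). That of FGFR2 was lost without DMSO replicate 1, 2 or 3 or IT848 replicate 1 or 2 of U266 (0.0502, 0.0529, 0.0543, 0.0581 and 0.0676). It was also lost per transcript as deposited (−3.06, adjusted p 0.192), with 1 transcript per gene (−3.04, 0.191), by limma-voom (−3.20, 0.0705) and without the 2 libraries (0.0697). That of LAMP5-AS1 was lost without DMSO replicate 1, 2 or 3 or IT848 replicate 1 of U266 or DMSO replicate 1 of MM.1S (0.0721, 0.0766, 0.0770, 0.106 and 0.0511), and without the 2 libraries (0.121). That of ARHGAP6 was lost without DMSO replicate 1, 2 or 3 of U266 (0.0694, 0.102 and 0.112), DMSO replicate 1, 2 or 3 of MM.1S (0.0715, 0.0593 and 0.0624) or IT848 replicate 1, 2 or 3 of MM.1S (0.0610, 0.0655 and 0.0934). It was also lost without the low-count filter (0.0977), and the ARHGAP6 difference was −2.32 without IT848 replicate 1 of U266. That of TP63 was lost without DMSO replicate 1, 2 or 3 (0.0687, 0.0682 and 0.0691) or IT848 replicate 1, 2 or 3 of U266 (0.0633, 0.0634 and 0.0629). It was also lost without DMSO replicate 1 or 2 (0.187 and 0.0727) or IT848 replicate 1, 2 or 3 of MM.1S (0.0703, 0.0949 and 0.0837). Per transcript as deposited the TP63 difference was −1.89 (adjusted p 0.433), with 1 transcript per gene −1.91 (0.440), and without the 2 libraries −4.59 (0.0955), and limma-voom gave an adjusted p of 0.103.

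List medians of the difference were 0.65 for NRF2 genes, −0.14 for ATF4 genes, 0.42 for proteasome genes, −0.28 for ribosome biogenesis genes, 0.30 for ribosomal protein genes, −0.45 for G1/S genes, 0.16 for G2/M genes, −0.13 for p53 targets, −0.17 for IL6-STAT3 targets, 0.40 for interferon-stimulated genes, −0.38 for immediate early genes, 0.26 for cholesterol genes, 0.23 for respiratory chain genes, 0.15 for lysosome genes and −0.55 for genes characteristic of MM.1S. With an estimated correlation 8 of these 15 stayed called; the adjusted p was 0.316 for ATF4, 0.0914 for proteasome, 0.609 for ribosomal protein, 0.443 for G2/M, 0.202 for IL6-STAT3, 0.664 for respiratory chain and 0.0914 for MM.1S genes. The ATF4 list was also lost without DMSO replicate 1 or 3 or IT848 replicate 1 or 3 of U266 (adjusted p of 0.151, 0.0575, 0.0502 and 0.110 by camera) and without DMSO replicate 2 or 3 or IT848 replicate 1 of MM.1S (0.0774, 0.0639 and 0.100). It was lost too with RLE scaling (0.0526), without the 2 libraries (0.0958) and with the length trend taken out (0.0668).

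In IT848 replicate 1 of U266, genes of MM.1S were read where U266 DMSO libraries had nearly none. The ratio to the MM.1S level was nearly constant over the 11 genes, with a 75th percentile 1.69 times the 25th, which is consistent with reads of MM.1S in this library. A response of U266 to IT848 is argued against, since the median ratio was 0.884% in this library and at most 0.0885% in the other two. In DMSO replicate 2 of MM.1S the ratio to the U266 level over 36 genes had a 75th percentile 1.81 times the 25th, so reads of U266 are a candidate source there. Among 695 genes over 32-fold higher in MM.1S, 35 were called higher with IT848 in U266, and 12 without the 2 libraries. Over all genes the rises called in U266 went from 676 to 421, so part of that drop may come from fewer libraries. Among 821 genes over 32-fold higher in U266, 24 were called lower with IT848 in MM.1S, and 10 without the 2 libraries. All falls called in MM.1S went from 3289 to 2688.

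In MM.1S, genes with short transcripts stood higher in the IT848 libraries, and this trend is a candidate cause of the rises of proteasome and ribosomal protein genes and of the fall of G1/S genes. The U266 libraries shifted the same way, with overlap between DMSO (0.0054 to 0.216) and IT848 (−0.277 to 0.123) in the correlation with transcript length. With the trend taken out, the ribosomal protein median went from 0.40 to 0.0991 (SD across genes 0.172) and the calls from 48 to 27 up and 2 down, so most of that rise may be the trend. The proteasome median went from 0.55 to 0.413, with all 33 genes still called higher, so part of that rise may be the trend. The G1/S median stayed at −0.465 with 41 of 42 lower. These values argue against the trend as the whole cause of either change. Whether the trend came from RNA handling or from the treatment was not tested. A response to IT848 stays open as a hypothesis for the proteasome and G1/S changes.

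About 4 times as many genes were called in MM.1S as in U266 (6430 against 1512), which a difference in depth, in spread or in the length trend could produce. With all libraries thinned to the smallest total the ratio of the counts was 4.41 (6371 against 1444), and with the length trend taken out 3.61, which argues against depth and length. Over 9197 genes the SD of the log2 fold changes beyond their errors was 1.78 times as large in MM.1S (0.319 against 0.179), at median errors of 0.0612 and 0.0608. These errors came from a dispersion per gene shared by all 12 libraries, so they cannot compare the spread of the lines. Library pairs within a group had a chi-square per degree of freedom of 2.00 to 4.91 in U266 and 2.83 to 25.7 in MM.1S. These values showed no larger spread in U266. With each line fitted alone, 2073 genes were called in U266 and 5831 in MM.1S. A larger response of MM.1S at this dose and time remains as a hypothesis, found and tested on the same data.

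Other splits of the samples were tried for each count. With 10 splits per line or of the DMSO libraries there were too few for a share under 0.05: 1 of 10 gave as many genes in U266 (1512; highest other 2), 1 of 10 in MM.1S (6430; highest other 1) and 1 of 10 for the line comparison (13868; highest other 0). For the difference of responses 4 of 100 splits gave 2924 genes or more, the real one included. This share is set by the kinds of split, so it does not tell a difference of responses from chance. The highest other, 3808, and the other 2 came from the 10 splits that mixed U266 libraries and kept the MM.1S labels, and so held the MM.1S response. The 81 splits that mixed both lines reached at most 1 and the 8 that mixed MM.1S at most 26, since they remove the response itself. For genes changed in both lines 1 of 100 splits gave as many (887; highest other 0). Mixing the labels of a line left it at most 2 calls, so these splits do not test whether the sharing exceeds chance.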

How the results depend on the processing

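The fits with 1 transcript per gene, without 2 libraries and with the length trend taken out were chosen only after the data were seen. Of 7242 values of genes named in the text under alternative settings, 264 changed their side of the threshold (151 lost, 113 gained) and 0 reversed. These genes were named mostly for large changes or small adjusted p, so the numbers do not describe genes at large. Of 1305 list values apart from NF-kB, 30 were lost, 28 gained and 1 reversed. That was the respiratory chain list in MM.1S, at an adjusted p of 0.957 with the length trend taken out, where its median was 0.04, since the fit removes the trend that short transcripts followed. Its other settings gave adjusted p-values of 1.7e-06 to 0.845. Other scalings, filters, DESeq2, limma-voom, separate fits and single transcripts kept every count within 1.5 times: 1360 to 2073 genes in U266, 5831 to 6962 in MM.1S, 2585 to 3560 for the difference, 789 to 1126 in both and 12046 to 14452 at baseline. DESeq2 gave no adjusted p for 2284 genes in U266.

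A 2-fold minimum left 96 genes in U266, 486 in MM.1S, 323 for the difference, 7145 at baseline and 26 in both, and a test against a 1.2-fold change 243, 1895, 642, 11672 and 121, since both ask for larger effects. Without the 2 libraries with reads of the other line the counts were 924 in U266, 1712 for the difference and 550 in both, with fewer samples. Leaving out each library gave 986 (without DMSO replicate 3) to 1264 genes in U266, 5110 to 6681 in MM.1S, 2208 to 3870 for the difference, 599 to 983 in both and 13480 to 13665 at baseline, and 10 to 12, 15 to 16 and 14 to 17 lists. With an estimated correlation 8 of 15 lists stayed called for the difference, and fry called 16 lists in U266 against 10, as it does not compare a list with other genes.

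The labels do not say that equal replicate numbers pair the samples, and the data pointed that way for most samples but not for all. Correlations of deviations between samples of the same number were 0.344, 0.338 and −0.0436 in U266 and 0.636, 0.0361 and 0.616 in MM.1S, over 5425 genes. Between different numbers they ran from −0.399 to 0.0594 in U266 and from −0.66 to 0.221 in MM.1S. DMSO replicate 3 and IT848 replicate 3 of U266 and IT848 replicate 2 of MM.1S did not correlate best with their own number, while the other samples did. The main tests took no account of pairing. With the replicate block the difference count was 4388 (cause not tested), with 2155 genes in U266, 7331 in MM.1S, 1271 in both and 13874 at baseline. The block also brought the ribosomal protein list in U266 past the threshold (adjusted p 0.0115), RELB in MM.1S (0.0211), CCL3 in U266 (0.0038), and HRH2, FGFR2, ARHGAP6 and LAMP5-AS1 in U266 (0.0032, 0.0051, 6.2e-05 and 0.0153 by edgeR's quasi-likelihood test), and ended the IL6 call in U266 (0.0586). In simulated data, which held fewer changed genes than were called here, 55.2 to 60.3% of 1.5-fold changes were recovered. This share does not carry over to the real data, but a gene without a call is not shown to be unaltered.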

Other observations

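No test in this part was chosen only after its result was seen, apart from the fits with 1 transcript per gene, without the 2 libraries that held reads of the other line and with the length trend taken out. Genes of cell survival changed in both directions. Of 33 BCL2 family, caspase and inhibitor-of-apoptosis genes, 5 rose and 8 fell in U266 (5 and 8 adjusted over the list alone), and 10 rose and 9 fell in MM.1S (12 and 9 adjusted over the list alone), and the list was not called (camera adjusted p 0.937 and 0.908). BCL2L11, which encodes the death-promoting protein BIM, fell by 0.21 ± 0.04 in U266 and 0.61 ± 0.04 in MM.1S. The survival gene MCL1 fell by 0.21 ± 0.04 and 0.31 ± 0.04. Genes characteristic of the lines fell too: CCND1 by 0.37 ± 0.08 in U266 (2 of 2 U266 genes lower, 2 adjusted over the list alone). The other of the 2, IL6, lost its call without any 1 of the 6 U266 libraries. Its adjusted p by edgeR's quasi-likelihood test was 0.124, 0.0906 and 0.142 without DMSO replicate 1, 2 or 3, and 0.143, 0.129 and 0.0683 without IT848 replicate 1, 2 or 3. IL6 was also not called without the low-count filter (0.0836), without the 2 libraries with reads of the other line (0.167) or by DESeq2 (0.0665). In MM.1S, CCND2 fell by 0.96 ± 0.05 and MAF by 0.39 ± 0.07 (2 of 3 MM.1S genes lower, 2 adjusted over the list alone), with an adjusted p of 4.5e-04 by camera and 0.0872 with an estimated correlation. In U266, 1 of these 3, CCND2 (−0.16), was called lower (1 adjusted over the list alone). By edgeR's quasi-likelihood test it was not called with upper quartile scaling (adjusted p 0.0565), with totals (0.0650), with the length trend taken out (0.107), without DMSO replicate 1 or 3 (0.127 and 0.0863) or without IT848 replicate 2 or 3 (0.0866 and 0.146). In MM.1S 1 of the 2 U266 genes (1 adjusted over the list alone).

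Fatty acid synthesis genes fell for 6 of 16 and rose for 2 in U266 (11 and 2 adjusted over the list alone; adjusted p 0.0019 by camera, 0.201 with an estimated correlation) and fell for 6 and rose for 3 in MM.1S (6 and 4 adjusted over the list alone; camera adjusted p 0.943). ME1, which NRF2 also controls, went against the fall with 0.66 ± 0.05 and 1.37 ± 0.05. Of 9 aryl hydrocarbon receptor targets, 2 rose and 0 fell in U266 (2 and 0 adjusted over the list alone; camera adjusted p 0.0021), and 2 rose and 1 fell in MM.1S (2 and 1 adjusted over the list alone; camera adjusted p 0.0072). NQO1, shared with the NRF2 list, had the largest called change of this list in both lines. In MM.1S that list's median was −0.05 although camera gave an upward direction. Hypoxia and glycolysis genes rose for 5 of 35 and fell for 2 in U266 (5 and 3 adjusted over the list alone) and rose for 12 and fell for 10 in MM.1S (12 and 11 adjusted over the list alone), not called by camera (adjusted p 0.937 and 0.340), while fry called them higher in MM.1S (adjusted p 0.0028). P4HA2 had the largest called rise of this list in both lines.

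Endoplasmic reticulum chaperone genes rose for 2 of 34 and fell for 6 in U266 (2 and 8 adjusted over the list alone; camera adjusted p 0.0695). Camera called the list lower in U266 with the length trend taken out (adjusted p 0.0281) and without IT848 replicate 3 (0.0474), and fry did so too (0.0056). In MM.1S the genes rose for 7 and fell for 10 (9 and 10 adjusted over the list alone; camera adjusted p 0.842). The medians of 4 metallothionein and zinc-response genes were 0.30 in U266 and 0.15 in MM.1S, and the list was not called (camera adjusted p 0.556 and 0.921), except higher in U266 by fry (0.0451). Of 15 histone genes 1 rose in U266 (2 adjusted over the list alone; camera adjusted p 0.0896), and the list was called higher there by fry (0.0299) and by camera with 1 transcript per gene (0.0489). In MM.1S their median was 0.14 (camera adjusted p 0.849). The list was lower in untreated MM.1S than in U266 (12 of 15 lower, 12 adjusted over the list alone, median −4.06; adjusted p 8.4e-07 by camera and 0.108 with an estimated correlation).

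Markers of other cells were at trace levels. Fibroblast and endothelial markers held 0.00407 to 0.0117% of counts, monocyte and macrophage markers at most 0.00340%, and epithelial markers at most 0.00111%. With IT848, 1 of 10 fibroblast and endothelial markers rose in U266 (5 rose and 1 fell adjusted over the list alone) and 3 in MM.1S (2 adjusted over the list alone), with camera adjusted p of 0.0748 and 0.257. The list was called higher in U266 by camera without DMSO replicate 3 (adjusted p 0.0394) or IT848 replicate 2 (0.0401), and by fry in U266 and MM.1S (0.0370 and 0.0163). Of 6 myeloid markers 1 rose in U266 (1 adjusted over the list alone), of 12 T and NK cell markers 1 in MM.1S (0 adjusted over the list alone), of 2 erythroid markers 1 in MM.1S (1 adjusted over the list alone). The list of 4 epithelial markers gave camera adjusted p-values of 0.761 in U266 and 0.838 in MM.1S, and camera did not call the myeloid and T and NK cell lists either, while fry called the myeloid list higher in U266 (adjusted p 0.0451).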
